A study of Mus musculus with 4 samples.

How the data were processed

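RNA was sequenced from mouse embryonic fibroblasts (MEFs) that carry both working copies of Mll1 (wild type, Mll1+/+) or that are labelled as lacking the gene (Mll1-/-). Mll1, now named Kmt2a, encodes a histone H3 lysine 4 methyltransferase. Cells of each genotype received tumour necrosis factor alpha (TNF) at 10 ng/ml or control solution for 4 hr. The series' design text gives this dose in ng/ml, whereas the treatment protocol gives the same figure in another unit, so the dose rests on the design text alone. Each treatment was carried out 3 times, and the cells of these 3 treatments were mixed before sequencing, per the series' design text. Each of the 4 groups is therefore 1 library. There are no replicate values, no spread between replicates could be measured, and no p-value or standard error between replicates is given anywhere.

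Per the labels' protocols, the submitters extracted total RNA with a spin-column kit, purified and fragmented the mRNA, made double-stranded cDNA, and ligated adapters. The submitters' processing notes name TopHat, a spliced-read aligner, and DESeq, a package for count data, without a version or a role for either. The genome build, the annotation and the program that counted reads are not given in the sources used here. The deposited values are RPKM (reads scaled to transcript length and to the library's total), per the file headers, with 1 value for each of 27344 transcript entries in each library. Strand is not mentioned in the labels, so reads from a gene and from an overlapping antisense gene cannot be separated.

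The RPKM values were made from whole reads, which allowed the depth to be recovered. For each transcript entry the deposited value equals the number of reads times the worth of 1 read, which depends on the transcript length and on the library's total. In 27340 of the 27344 entries (99.99%) a single length gave whole numbers of reads in all 4 libraries, within 0.0001 reads. The totals recovered were 27728647 reads for the wild-type control library, 27977248 for wild type with TNF, 20081869 for the Mll1-/- control and 19306506 for Mll1-/- with TNF. The reads summed over all entries came to between 1.635 and 1.732 times those totals, which would follow if reads were counted for several transcript entries of a gene, though this was not tested. The recovered lengths lay within 10% of the length of the same transcript in GENCODE M21 for 78.0% of 16972 entries. For 673 entries the reads were multiplied by a whole number to match that length, and elsewhere the recovered reads are a lower bound. Ratios of reads carry 95% exact binomial intervals (Clopper-Pearson), called counting intervals here, and the difference in response carries a normal interval of the log2 ratio of read ratios. A value of 0 is treated as up to 3 reads in that library, which gives "at least" folds. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

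Entries were named through their transcript accession, 20849 by a RefSeq gene table made on GRCm38.p6 and 102 by GENCODE metadata. The table was used for names and for which genes neighbour each other, and no coordinates are given because the build behind the deposited values is not stated. The 6393 entries without a name were kept. Where a symbol had several entries, the entry with the highest mean RPKM over the 4 libraries was used. Exactly the same 4 values were found in another entry for 3106 entries, and members of multigene families with shared reads, such as the Prl2c and histone H4 genes, are reported as uncertain.

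All comparisons used log2(RPKM + 0.5), which understates the change of genes near the floor. Genes with at least 1 RPKM in at least 1 of the 4 libraries were compared, which left 14386 genes and unnamed entries, 11115 of them with a symbol. A gene was counted as past the size rule when its log2 ratio was 1 or more in size, which is a 2-fold difference on that scale. The comparisons were TNF against control in each genotype, Mll1-/- against wild type without and with TNF, and the difference between the log2 TNF ratio in Mll1-/- and that in wild type. The last was counted over genes past the size rule upward in either genotype. Genes are named by rule: the 10 highest and the 10 lowest log2 ratios among genes past the size rule with at least 3 RPKM in the higher library, the same for the difference in response, up to 4 members of each gene list described (the 2 highest and the 2 lowest), and the methyltransferases of the Mll1 family. Predicted genes, small RNAs and unnamed entries were counted but not named. A gene named outside this rule is said to have been chosen after its values were seen.

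There were 36 gene lists with 683 symbols, of which 11 stood in more than 1 list, all taken from general knowledge. For each list the members past the size rule were counted, and the list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That place describes these libraries and is not a test. No symbol of the list of mitochondrially encoded genes was found, and those genes are not analysed here. The size rule, the lists, the rule for names and most of the alternatives described below were fixed before the data were examined.

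The steps were tested on counts simulated from each entry's mean share of reads over all 4 libraries and from the 4 library totals. Differences were planted only in genes with a mean of at least 2 RPKM. Of genes made different between the wild-type libraries, 0 of 47 at 1.5-fold, 12 of 48 at 2-fold, 48 of 48 at 4-fold and 48 of 48 at 8-fold passed the size rule, so a true 2-fold difference is missed more often than found. Of 13854 unchanged genes in that simulated comparison, 25 passed the rule through counting error alone, and 3 of those also had a counting interval that excluded 1. In the simulated comparisons of Mll1-/- with TNF against its control, of the genotypes without TNF and of the genotypes with TNF, 34, 25 and 37 unchanged genes passed. The counting interval held the true ratio for 95.5% of genes. Read recovery, run on 1959 simulated entries, gave whole reads in 100.0% and exactly the drawn reads in 96.0%.

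The alternatives tried were other pseudocounts, floors and fold thresholds, 3 other scalings between libraries, entries kept apart, the counting interval as a further requirement, other gene sets for the difference in response, and the increase in RPKM in place of the log2 ratio. After the data were seen, removal of the trend of each log2 ratio on transcript length (lowess with a fraction of 0.3 and 3 iterations), restriction to genes with a symbol and restriction to transcripts of at least 300 bases were added. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Some results, including 1 test of a group of neighbouring genes, are not reported here.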

Results

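TNF drives inflammatory gene expression in fibroblasts through NF-kB, and Mll1 methylates histone H3 lysine 4 at the promoters of many genes, among them the Hox genes. In wild-type MEFs given TNF for 4 hr, the transcripts that were higher by the largest ratios encode chemokines that recruit lymphocytes and neutrophils, a leukocyte adhesion molecule, secreted defence proteins and feedback regulators of NF-kB. The same classes of gene were higher with TNF in the cells labelled Mll1-/-, so the NF-kB response was present in those cells. For the genes that responded most, the ratio was smaller in Mll1-/- cells in the majority of cases. The cells also differed in a far larger set of genes without TNF, including the Hoxc and Hoxd clusters and the extracellular matrix. Each group is 1 library, so every difference below is a description of 4 libraries and none has been tested.

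In wild-type cells, 75 genes or unnamed transcripts were higher with TNF past the size rule and 8 were lower, and the middle 95% of all log2 ratios lay between -0.37 and 0.45. Counting intervals excluded 1 for 64 of the higher but only 2 of the lower, so the lower count is within what counting error gives. Ccl20, which attracts lymphocytes and dendritic cells through Ccr6, went from 1.69 RPKM in the control library to 56.3 with TNF, a 33.3-fold ratio (counting interval 24.3 to 46.8). Cxcl1 and Cxcl5, both ligands of the neutrophil receptor Cxcr2, stood at 18.6 and 24.99 RPKM in the control and at 320 and 338 with TNF (log2 4.07 and 3.73). Vcam1, to which leukocytes bind through integrins, was 16.3-fold higher (1.31 against 21.3 RPKM), and Cxcl10, a T-cell attractant, was 13.2-fold higher (0.407 against 5.38). The acute-phase protein gene Saa3 had 2 reads in the control library and 69 with TNF (34.2-fold, counting interval 9.11 to 288), and Lcn2, whose product withholds iron from bacteria, was 9.09-fold higher. Regulators of the pathway itself complete the 10 genes named by rule: the receptor adaptor Traf1 (1.64 against 10.7 RPKM, log2 2.38), the A20-binding inhibitor Tnip3 (0.249 against 3.22, log2 2.31) and the NF-kB inhibitor gene Nfkbie (1.10 against 6.82, log2 2.19). None of the genes that were lower had 3 RPKM in the higher library and a name that the rule admits.

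**Figure D1:**
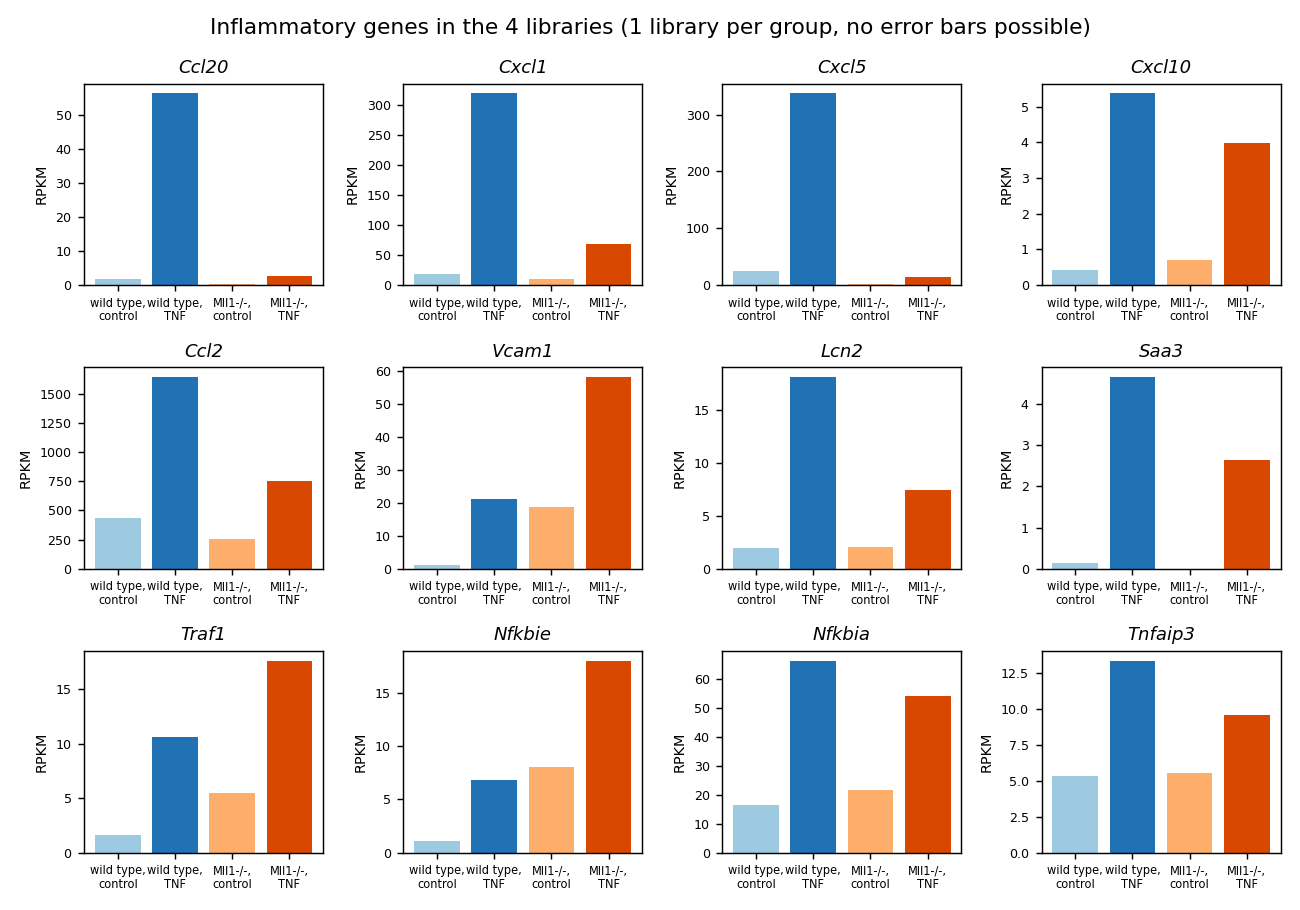
RPKM of 12 chemokine, adhesion, secreted and NF-kB pathway genes in the 4 libraries, with and without TNF.

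By gene group, the wild-type response was that of NF-kB. Of 21 measured genes for NF-kB family members and feedback inhibitors, 11 were higher and 0 lower, with a median log2 ratio of 1.10 that lay above all 10000 random lists. Traf1 and Tnip3 led the group, while Tnip2 (4.92 against 4.67 RPKM) and the ubiquitin ligase gene Birc2 (7.85 against 8.28) were the lowest. Among 10 measured chemokines 6 were higher and 0 lower (median 1.86, above 10000 random lists), from Ccl20 and Cxcl1 down to Cx3cl1 (log2 0.61) and the homeostatic chemokine Cxcl12 (-0.32). Of 14 adhesion and cell-surface genes 3 were higher and 0 lower (median 0.58), namely Vcam1, the death receptor gene Fas (2.45 against 9.72 RPKM) and the interleukin-33 receptor gene Il1rl1 (24.9 against 53.3), with Cd44 (log2 0.26) and the bacterial lipoprotein receptor Tlr2 (0 and 3 reads) at the low end. Of 13 secreted and enzymatic effectors 5 were higher and 0 lower (median 0.87, above 10000 random lists). Saa3 and Lcn2 were the highest of these, and the complement factor gene Cfb (log2 0.02) and the phospholipase gene Pla2g4a (0.09) the lowest.

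Other groups moved little in wild-type cells. Of 9 cytokine genes 1 was higher and 0 lower (median 0.15): Il6, the fever and acute-phase cytokine, at 1.23 against 4.998 RPKM, followed by Lif (3.05 against 6.51, log2 0.98), with Inhba (-0.20) and Tnfsf9 (-0.18) lowest. Of 12 matrix metalloproteinase genes and inhibitors 2 were higher and 0 lower, Mmp10 (0.231 against 1.43 RPKM) and Mmp13 (0.135 against 1.14), which degrade matrix in inflamed tissue, and the median (-0.13) and the mean (0.19) differ in sign, with Timp3 (-0.36) and Mmp19 (-0.19) lowest. Of 13 interferon-stimulated genes 1 was higher and 0 lower (median 0.08), the guanylate-binding protein gene Gbp2 at 0.263 against 1.65 RPKM. The 12 genes of MHC class I antigen presentation held none past the size rule, although their median of 0.25 lay above 10000 random lists, with the peptide-loading gene Tapbp at 0.65. Among 21 immediate-early genes 1 was higher and 0 lower, the survival gene Ier3 (15.2 against 34.4 RPKM), and 0 of 25 genes for TNF receptor signalling proteins were past the size rule in either direction.

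In Mll1-/- cells, 99 genes or unnamed transcripts were higher with TNF past the size rule and 23 were lower, of which 81 and 7 had a counting interval that excluded 1. In the simulation of this comparison 34 unchanged genes passed the rule, both directions together. Counting error could therefore give many of the lower genes, but not clearly all of them. Cxcl1 (9.14 against 68.0 RPKM, 7.43-fold) and Cxcl5 (1.99 against 14.6, 7.33-fold) led the named genes, and Cxcl10 was 5.69-fold higher (0.703 against 4.00). The monocyte attractant Ccl2 went from 255 to 752 RPKM (log2 1.56), compared with 434 to 1643 in wild-type cells (log2 1.92). Vcam1 (18.8 against 58.3 RPKM), Fas (3.69 against 13.0), Lcn2 (2.04 against 7.41) and Traf1 (5.50 against 17.6) were each between 3.10-fold and 3.63-fold higher. The host gene of small nucleolar RNAs Snhg9 was 13.5-fold higher on 1 read in the control library (counting interval 2.03 to 575), and the inhibitory receptor gene Lilrb4a (1.86 against 6.64 RPKM) may share reads with its close relatives. As in wild type, no gene that was lower could be named by the rule. The tally of all genes depends on the length trend described below: with that trend removed 61 genes were higher and 58 lower. With the 20 most abundant genes left out of the scaling, which shifts the median of this comparison by -0.15, 73 were higher and 38 lower. Median-ratio and upper-quartile scaling shift that median by only -0.027 and -0.031.

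The gene groups of the Mll1-/- response were those of wild type, with smaller medians for NF-kB, chemokine, adhesion and effector genes. Of 21 NF-kB pathway genes 7 were higher and 0 lower (median 0.73, above 10000 random lists), from Traf1 and Tnip3 (2.02 against 6.79 RPKM) to the deubiquitinase gene Cyld (12.8 against 11.6) and Tnip2. Of 10 chemokines 6 were higher and 0 lower (median 1.46, above 10000 random lists), with Ccl17 (0.61) and Cxcl12 (-0.16) lowest. Of 14 adhesion and cell-surface genes 3 were higher and 0 lower (median 0.37), the third after Fas and Vcam1 being Tlr2 (1.32 against 4.27 RPKM), and the cytokine receptor genes Il1r1 (-0.16) and Il4ra (-0.15) were lowest. Of 13 effectors 3 were higher and 0 lower (median 0.44): Saa3, with 0 reads against 27 and so at least 9.36-fold higher, Lcn2, and Gch1 (log2 1.29), which makes the cofactor of nitric oxide synthase. Of 9 cytokines 2 were higher and 0 lower (median 0.45), Lif (3.67 against 9.25 RPKM) and Il6 (1.10 against 2.76), with Fgf2 (-0.49) and Il33 (-0.45) lowest. Mmp13 (3.09 against 8.48 RPKM) was the 1 metalloproteinase gene of 12 past the size rule. Of 13 interferon-stimulated genes 2 were higher and 0 lower, Gbp2 (0.685 against 2.75 RPKM) and the virus-tethering gene Bst2 (0.403 against 1.32). MHC class I genes had a median of 0.42 over 12 members with 0 past the size rule, with H2-T23 at 0.89 and the light chain gene B2m at 0.74 (218 against 364 RPKM). Ier3 (27.5 against 58.5 RPKM) was again the 1 immediate-early gene of 21 past the size rule. With the length trend removed, Ier3 (0.90), Il6 (0.85) and Bst2 (0.80) were no longer past it in Mll1-/- cells, and 6 rather than 7 NF-kB pathway genes were.

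Between the genotypes, the strongest TNF responders had smaller ratios in Mll1-/- cells, and a separate group of mostly short transcripts had larger ones. Of the 27 genes past the size rule upward in both genotypes, where 0.52 would be shared by independent lists of those sizes, 25 had the smaller log2 ratio in Mll1-/- cells, with a median difference of -0.37. Ccl20 had the lowest value: 1.69 to 56.3 RPKM in wild type and 0.292 to 2.49 in Mll1-/- (5 and 41 reads), a difference of -2.78. From reads without the pseudocount in RPKM it was -2.07 (interval -3.43 to -0.71), and Neurl3 (-2.62) and Vcam1 (-2.39) lay lower. Neurl3, a ubiquitin ligase gene induced in inflammation, went from 1.47 to 7.32 RPKM in wild type and from 1.29 to 1.04 in Mll1-/- (-2.21). Vcam1 (-1.98), Lcn2 (-1.26), Cxcl1 (-1.24), Cxcl5 (-1.13) and Nfkbie (-1.08) followed. The antiviral gene Samd9l was 6.55 and 14.3 RPKM in wild type but 0.513 and 0.514 in Mll1-/- (-1.06, and -0.91 once the length trend is removed). The 5S ribosomal RNA entry Rn5s (-2.29) and the multicopy placental hormone gene Prl2c1 (-0.92) also rank among the 10 lowest, but both are uncertain because of their shared reads.

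**Figure D2:**
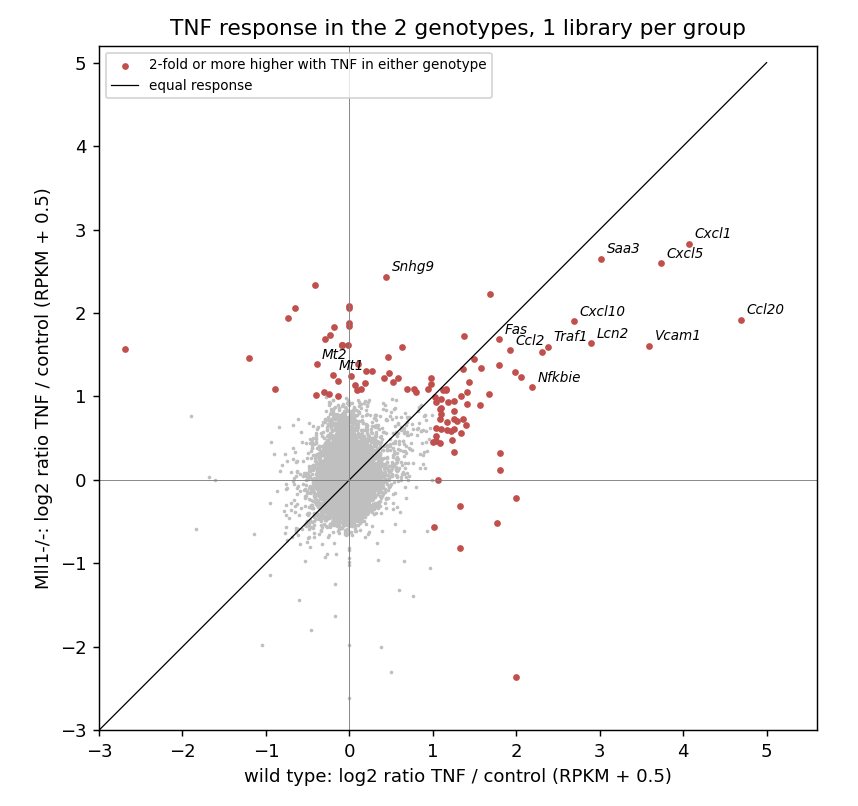
Log2 TNF ratio of each gene with a symbol in wild-type (horizontal) and Mll1-/- cells (vertical), with the genes past the size rule upward in either genotype in red. The line marks equal responses.

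At the level of groups, the NF-kB, chemokine, effector and adhesion lists had median differences below 0, with most members within the size rule. The 21 NF-kB pathway genes had a median difference of -0.36, with 0 of 10000 random lists below it, and 1 member, Nfkbie, was lower by the size rule and 0 higher, while Nfkbib (0.32) and Birc2 (0.18) were the highest. The 10 chemokines had a median of -0.39 (0 random lists below) with 3 lower and 0 higher, or -0.64 with 4 lower once the length trend is removed. Cxcl5, 1 of the 3, was at -0.89 from reads. Ccl20 and Cxcl1 were the lowest of them and Cxcl12 (0.16) and Ccl9 (0.04) the highest. Of 13 effectors 3 were lower and 0 higher (median -0.37), with the protease inhibitor gene Serpina3g at -1.69 and the nitric oxide synthase gene Nos2 at -1.48, against Gch1 at 0.81. Nos2 had 0 reads in the wild-type control and 139 with TNF (at least 45.9-fold), and 1 and 11 reads in Mll1-/- (11.4-fold, counting interval 1.66 to 493). Of 14 adhesion genes 1 was lower (Vcam1) and 1 higher (Tlr2, 1.29, a value whose direction turns without the pseudocount), with a median of -0.24.

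The smaller ratio has its limits as a statement about Mll1-/- cells. Over the 47 genes with a mean log2 response of 1 or more, the median difference was -0.36 and 37 lay below 0, but only 24 had the smaller increase in RPKM. Vcam1 is the clearest such case, since it started at 18.8 RPKM in Mll1-/- and gained 39.5 RPKM with TNF, against 19.96 in wild type, and Nfkbie gained 9.95 against 5.72. Cxcl1 (58.8 against 301 RPKM gained), Cxcl5 (12.6 against 313), Ccl20 (2.20 against 54.6) and Lcn2 (5.36 against 16.1) gained less on both scales. For Cxcl1, Cxcl5 and Ccl20 the smaller gain is not separate evidence. They started lower in Mll1-/- cells (9.14 against 18.6, 1.99 against 24.99 and 0.292 against 1.69 RPKM). With a smaller ratio as well, a smaller gain follows by arithmetic. Lcn2 started at a similar level (2.04 against 1.99 RPKM), and its response was smaller by either measure. For Vcam1 and Nfkbie the answer depends on the scale.

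Larger responses in Mll1-/- cells were found for several short transcripts, among them those of the metallothionein genes Mt2 and Mt1 (556 and 583 bases). Of the 147 genes and unnamed transcripts past the size rule upward in either genotype, 48 had a response higher by 1 or more in Mll1-/- and 20 a response lower by 1 or more, with a median of 0.06. Restricted to the 110 with a symbol the numbers were 31 and 15 with a median of -0.12. The metallothionein genes Mt2 (2.85 to 2.06 RPKM in wild type, 14.6 to 39.0 in Mll1-/-, difference 1.78) and Mt1 (86.4 to 75.3, and 52.4 to 126, 1.45), which buffer zinc, had differences above 1, and Tlr2 went from 1.32 to 4.27 RPKM in Mll1-/- with 0 and 3 reads in wild type. Snhg9 (5.91 to 8.20 RPKM, and 0.272 to 3.68), Pnkd (1.42), the respiratory chain genes Uqcr11 (1.31) and Cox17 (1.07), the amidase gene Wdyhv1 (9.27 to 13.0 RPKM, and 2.72 to 8.42), and the histone genes H4c18 (1.36) and H4c3 (1.28), whose copies share reads, complete the 10. Removal of a trend with transcript length left 22 of the 48. With upward genes picked again on the corrected ratios, the median was -0.39 in place of 0.06. How much of that shift comes from the change of gene set was not measured. Once the trend was removed, Uqcr11 (0.97), Cox17 (0.73), Wdyhv1 (0.72), H4c18 (0.98) and H4c3 (0.89) dropped below a difference of 1. Mt2 (1.47), Mt1 (1.15), Tlr2 (1.30), Snhg9 (1.57) and Pnkd (1.13) stayed above it. The value of Tlr2 rests on the pseudocount, because its 0 and 3 wild-type reads give a read-based difference of -1.10 with an interval of -5.39 to 3.19.

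The length trend involves the Mll1-/- libraries. From the shortest to the longest decile of transcripts, the median TNF ratio went from 0.31 to -0.20 in Mll1-/- cells and from -0.01 to 0.03 in wild type. The genotype difference went from -0.53 to 0.26 without TNF and from -0.17 to 0.02 with TNF, so the trend is widest in the comparisons that hold the Mll1-/- control library. Ribosomal proteins, which have short transcripts, show what it does: of 30 such genes 0 were past the size rule for TNF in either genotype, yet the median was 0.33 in Mll1-/- cells (0.11 with the trend removed, 0.16 with the 20 most abundant genes left out) against -0.08 in wild type.

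**Figure D3:**
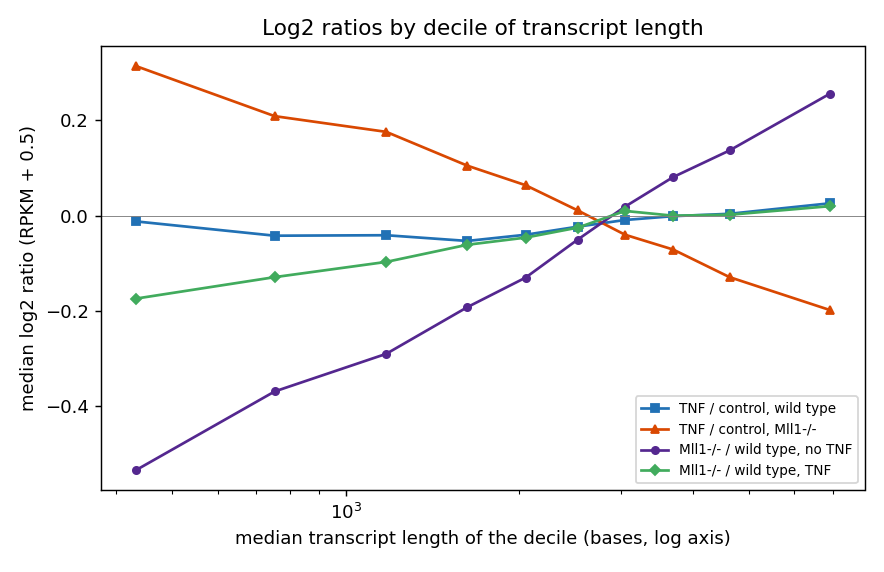
Median log2 ratio by decile of transcript length in the TNF and genotype comparisons.

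The genotype difference was much larger than the TNF response. Without TNF, 1023 genes or unnamed transcripts were higher in the Mll1-/- library past the size rule and 1150 were lower. With TNF, 966 were higher and 647 lower. Both lists shared 817 higher and 542 lower genes, where 68.7 and 51.7 would be shared by independent lists. The log2 differences of the pairs, which have no library in common, had r = 0.911 across genes. Both pairs set Mll1-/- cells against wild-type cells and differ only in TNF. A large overlap would thus arise from any lasting difference between the cells and does not replicate an effect of genotype. The split of the genotype difference without TNF into genes higher and genes lower depends on the processing. With the 20 most abundant genes left out and the sums of RPKM made equal, the median shifts by 0.28 and 1529 are higher and 623 lower. Median-ratio and upper-quartile scaling shift that median by only 0.083 and 0.052. With the length trend removed 1181 are higher and 704 lower. With TNF, leaving out the 20 most abundant genes shifts the median by 0.10.

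Cd34, Cadm1 and Cxcl12 led the genes that were higher in Mll1-/- cells. Cd34, a sialomucin of mesenchymal and blood progenitors, stood at 0.307 RPKM in wild type and 246 in Mll1-/- (801-fold, counting interval 524 to 1295). Cadm1, a cell adhesion molecule, was 1181-fold higher (0.0414 against 48.9 RPKM), Cxcl12, which retains progenitor cells in their niche, 135-fold higher (0.672 against 90.8), the secreted neural protein gene Olfm1 453-fold higher (0.0671 against 30.4) and the brain creatine kinase gene Ckb 146-fold higher (0.268 against 39.2). The tight-junction gene F11r and the small heat shock protein gene Hspb1 had 0 reads in the untreated wild-type library and 26.04 and 24.1 RPKM in Mll1-/-, which is at least 597-fold and at least 203-fold. Ramp3, a receptor partner (1036-fold, counting interval 185 to 40960, on 1 read), Mmp3, a stromal protease (643-fold, 178 to 5321, on 2 reads), and Ifi202b, a DNA sensor of the interferon system (614-fold, 110 to 24320, on 1 read), complete the list without TNF. With TNF the crosslinking enzyme gene Tgm2 (0.0906 against 30.1 RPKM, 332-fold) joins the 10 highest.

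Among the genes lowest in Mll1-/- cells were Bgn, Mmp2 and Selenop. Bgn, the small proteoglycan biglycan, stood at 582 RPKM in wild type and 5.71 in Mll1-/- (102-fold lower, counting interval 90.6 to 115), and Mmp2, the gelatinase of resting fibroblasts, was 119-fold lower (48.3 against 0.406). Selenop, which carries selenium in plasma, was 231-fold lower (130 against 0.564 RPKM). Mgp, an inhibitor of calcification, had 1 read in Mll1-/- (61.6 RPKM in wild type, 759-fold lower, 136 to 30010), as did the cornified envelope gene Sprr1a (92.6 RPKM, 1501-fold, 269 to 59330) and the lactate dehydrogenase subunit gene Ldhb (19.4 RPKM, 515-fold, 92.1 to 20370). The elastic-fibre gene Efemp1 had 3 reads (22.6 RPKM, 308-fold, 105 to 1497). Pcbd1, which recycles the tetrahydrobiopterin cofactor, the anticoagulant receptor gene Thbd and the phosphodiesterase gene Smpdl3b had 0 reads in Mll1-/- and were at least 465-fold, at least 496-fold and at least 241-fold lower. The same 10 genes were the lowest with TNF.

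**Figure D4:**
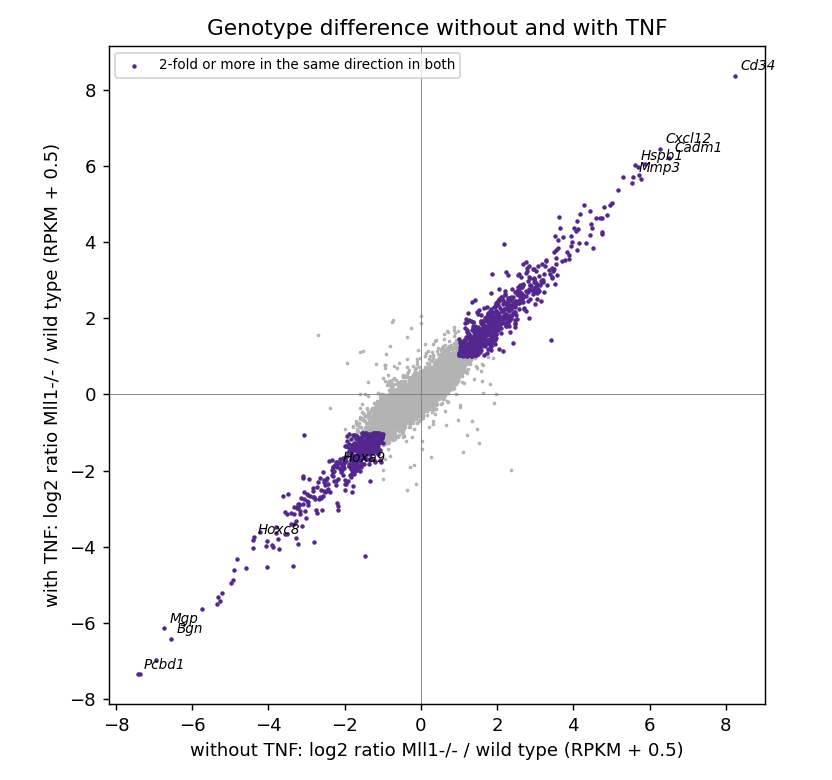
Log2 difference between Mll1-/- and wild type of each gene without TNF (horizontal) and with TNF (vertical), with genes past the size rule in the same direction in both in purple.

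Hox genes, the best-known targets of Mll1, differed by cluster. All 5 measured Hoxc genes were lower in Mll1-/- cells without TNF (median -3.06, with 0 of 10000 random lists below) and all 5 with TNF (median -2.57). Hoxc8 had 11.1 RPKM in wild type and 2 reads in Mll1-/- (263-fold lower, counting interval 72.5 to 2175), Hoxc9 went from 10.9 to 0.116 RPKM, and Hoxc10 (-2.39) and Hoxc5 (-1.65) were the least affected. Of 7 Hoxb genes 3 were lower and 0 higher without TNF (median -0.95) and 2 lower with TNF (median -0.47), with Hoxb6 at 7.33 against 0.482 RPKM and Hoxb9 at 35.2 against 9.81, while Hoxb4 was at 0.59. In the Hoxa cluster 3 of 8 were lower and 1 higher in both comparisons, with medians of 0.01 without TNF (mean -0.48) and -0.01 with TNF (0.07 with the 20 most abundant genes left out): Hoxa9 and Hoxa10 had 0 reads in the untreated Mll1-/- library (at least 27.3-fold and at least 18.4-fold lower), and Hoxa4 was higher (0.425 against 1.40 RPKM). Both measured Hoxd genes ran the other way, Hoxd8 at 1 read against 13.1 RPKM (516-fold higher, 92.1 to 20450) and Hoxd9 at 0.184 against 3.10.

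**Figure D5:**
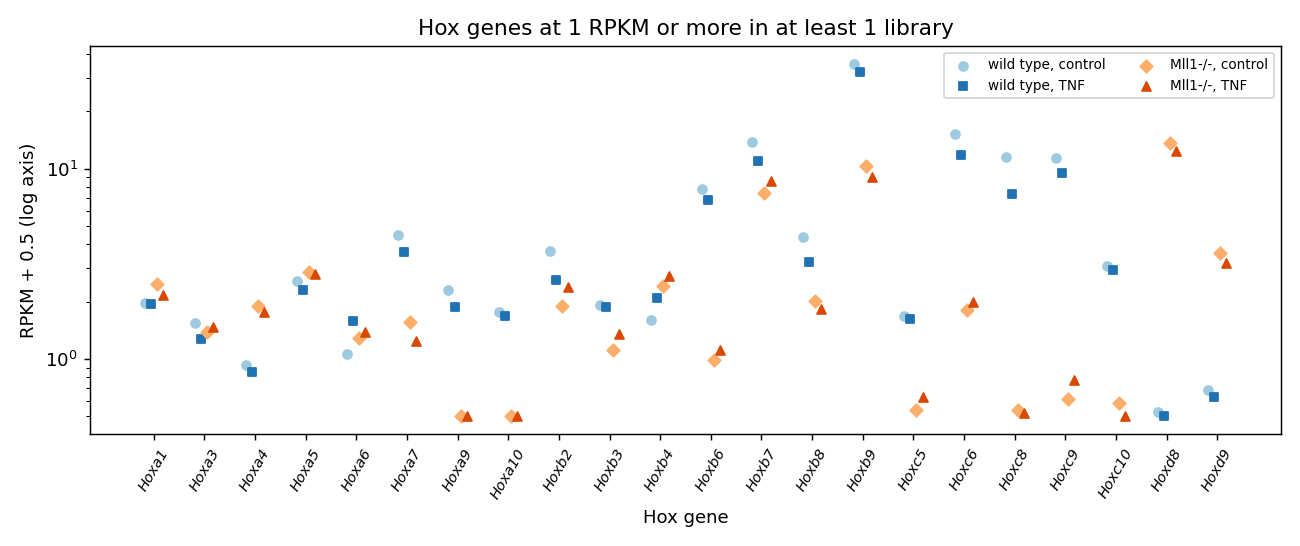
RPKM of the 22 measured Hox genes in the 4 libraries, on a log scale.

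Expression of Mll1 itself was within the size rule between the genotypes. Kmt2a had 1.85 and 2.11 RPKM in wild type without and with TNF and 2.02 and 1.66 in Mll1-/-, and once the length trend is removed it was lower in Mll1-/- by a log2 difference of -0.28 without TNF and -0.29 with it. A difference this small does not check the genotype, and a deletion that leaves most of the transcript would give the same values. Its relatives Kmt2b (3.01 against 3.55 RPKM without TNF), Kmt2d (2.67 against 4.395) and Setd1a (7.24 against 9.61) were within the size rule. None of the 18 measured methyltransferases of this family and partners was past it in any of the 4 comparisons, so no relative was higher by that rule in the cells labelled as lacking Mll1. Kmt2c was below 1 RPKM in every library.

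Developmental regulators and matrix genes differed along with the Hox genes. Of 22 Hox cofactors and other developmental transcription factors 6 were higher and 4 lower without TNF (5 and 3 with TNF, and also without TNF once the length trend is removed), from the lateral mesoderm factors Foxf1 (0.442 against 8.63 RPKM) and Osr1 (0.480 against 5.53) to Gata6, with 0 reads in Mll1-/- (at least 57.7-fold lower), and Foxd1 (12.9 against 3.38). Among 24 extracellular matrix genes 7 were higher and 5 lower without TNF (median 0.50) and 8 higher and 5 lower with TNF (median 0.41). The fibrillar collagen gene Col3a1 was 52.9-fold higher, the proteoglycan decorin (Dcn) had 0 reads in wild type and 9.16 RPKM in Mll1-/- (at least 160-fold), while Bgn and the collagen VI gene Col6a2 (55.1 against 7.26 RPKM) were lowest. Chosen after their values were seen, both chains of collagen I were higher (Col1a1 105 against 337 RPKM, Col1a2 32.2 against 199). The 15 contractile and serum response genes held 3 higher and 0 lower without TNF (median 0.50, with 5 higher once the length trend is removed) and 4 higher and 0 lower with TNF (0.57), with the tropomyosin gene Tpm2 at 3.20 against 114 RPKM and the smooth-muscle actin gene Actg2 at 1.51 against 5.16, against Ccn2 (-0.34) and Tagln (-0.25). Of 12 metalloproteinase genes and inhibitors 5 were higher and 1 lower (median 0.82, or 4 and 1 once the length trend is removed; 5 and 2 with TNF, 0.87), with Mmp3 and Mmp10 (0.231 against 19.2 RPKM) highest and Mmp2 and Mmp14 (41.1 against 20.7) lowest. Of 5 neural markers 4 were higher and 0 lower in both comparisons, among them the intermediate filament gene Nes (5.18 against 61.4 RPKM) and Map2, a microtubule-binding gene (1 read against 8.12 RPKM, 1247-fold, 223 to 49300).

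Cell-cycle inhibitors and p53 targets leaned lower in Mll1-/- cells. Of 21 cell-cycle inhibitors and p53 targets 8 were lower and 2 higher without TNF (median -0.72, with 1 random list below), or 5 and 2 once the length trend is removed, and 5 lower and 2 higher with TNF (median -0.55). The membrane protein gene Perp (11.6 against 0.236 RPKM) and Trp53inp1 (6.56 against 1.99) were lowest, and the death gene Pmaip1 (1 read against 3.53 RPKM, 260-fold, 46.0 to 10310) and Cdkn2b (3.42 against 9.55) highest. A pair of p53 targets chosen after their values were seen, Mdm2 (123 against 47.6 RPKM) and Ccng1 (344 against 147), were lower as well. Of 22 stress response genes 4 were lower and 1 higher (median -0.36, with 1181 random lists below; 3 and 1 with TNF, -0.20), including Trib3 (50.8 against 11.6 RPKM) and the glutathione-degrading enzyme gene Chac1 (64.6 against 15.9), against the lipoprotein receptor gene Vldlr (2.70) and Cth (0.66). Of 32 DNA replication and mitosis genes 4 were higher and 0 lower (median 0.11), or 3 and 0 once the length trend is removed. Ribosomal proteins had a median of -0.67 with 3 of 30 lower, which moved to -0.31 with 0 past the size rule once the length trend was removed.

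Inflammatory genes were set at other levels before TNF was added. Of 14 adhesion and cell-surface genes 6 were higher and 1 lower in untreated Mll1-/- cells (median 0.71), with the TNF receptor gene Tnfrsf1b (1.97 against 27.3 RPKM) and Vcam1 (1.31 against 18.8) highest and Il1rl1 (24.9 against 2.46) and the platelet selectin gene Selp (-0.67) lowest. Of 9 cytokines 0 were higher and 1 lower, Il33, the ligand of Il1rl1 (30.0 against 1.81 RPKM), so ligand and receptor were lower together. Of 10 chemokines 2 were higher and 2 lower without TNF (median -0.39, mean 0.40, or 3 and 2 with a median of -0.21 once the length trend is removed), Cxcl12 and Cx3cl1 (0.310 against 12.2 RPKM) against Cxcl5 (24.99 against 1.99) and Ccl20 (1.69 against 0.292), and with TNF 2 were higher and 5 lower (median -0.76, with 1 random list below). The 13 effectors held 3 higher and 1 lower without TNF (median 0.03, or -0.04 once the length trend is removed), with the complement genes C3 (2.23 against 30.7 RPKM) and C1s1 (2.34) highest and the prostaglandin synthase gene Ptges (3.45 against 0.150) lowest, and 3 higher and 4 lower with TNF (median -0.40). Of 13 interferon-stimulated genes 5 were lower and 1 higher without TNF (median -0.34), or 3 and 1 once the length trend is removed, with Irgm1 (15.2 against 3.29 RPKM) and Ifi35 (7.37 against 1.43) lowest and the RNA sensor gene Ddx58 (2.19) highest. The Mll1-/- culture thus carried more TNF receptor 2, Vcam1 and complement transcript at rest, and less Ccl20, Cxcl1, Cxcl5 and Ccl2 transcript with TNF.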

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

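Chosen after the result was seen were the narrowed rule for opposite responses described here and the removal of the length trend. TNF responses that ran in opposite directions in the genotypes were looked for among 224 genes named or eligible as examples for TNF. A first rule, that both counting intervals exclude 1, gave 35 such genes, and 1684 of all 14386 genes at the floor, and was too loose to be useful with small ratios at high depth. It was narrowed, once values had been seen, to genes that were also past the size rule in at least 1 genotype. The narrowed rule was applied to all genes whose names are admitted and that had at least 3 RPKM in at least 1 library, not only to the 224. It gave 3 genes. The metallothionein gene Mt1 had a log2 ratio of -0.20 in wild type and 1.25 in Mll1-/- (difference 1.45). Pnkd, whose product acts in glutathione metabolism, had -0.40 and 1.02 (difference 1.42), and Uqcr11, a subunit of respiratory complex III, had -0.13 and 1.18 (difference 1.31).

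All 3 transcripts are short, at 583, 642 and 436 bases, and short transcripts as a class had higher TNF ratios in the Mll1-/- pair. Once the length trend was removed the differences were 1.15 for Mt1, 1.13 for Pnkd and 0.97 for Uqcr11, and none of the 3 was still past the size rule in Mll1-/- cells (0.98, 0.76 and 0.86). Part of each opposite response could therefore follow the length trend, without which 22 of the 48 genes with a larger response in Mll1-/- remain, and whether that trend arose in the libraries or in the cells is open. No test of the difference between the genotypes is possible with 1 library per group.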

How the results depend on the processing

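Chosen after the result was seen were the removal of the length trend, the restriction to transcripts of at least 300 bases and the restriction to genes with a symbol. No paired analysis was possible because each group is 1 library without replicates to pair, and a fit of genotype and TNF as separate effects would have to take the difference in response as its error. With 1 library per group, leaving out a replicate was not possible either. The pseudocount, the floor and the fold threshold set how many genes count as different, most of all among genes near the floor. As deposited, the counts higher and lower were 75 and 8 for TNF in wild type, 99 and 23 for TNF in Mll1-/-, 1023 and 1150 for genotype without TNF, and 966 and 647 with TNF. Of the genes past the size rule upward in either genotype, 20 had a lower and 48 a higher response in Mll1-/- (median 0.06). Of the genes past it downward, 20 and 6 did.

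With a pseudocount of 0.1 RPKM the TNF counts were 126 and 30 in wild type and 158 and 65 in Mll1-/-, with 38 upward genes lower and 82 higher in response, and 46 downward genes lower and 17 higher. A pseudocount of 1 RPKM gave 5 lower in wild type, 11 lower in Mll1-/- and 9 downward genes lower in response. With a floor of 5 RPKM, 1 gene was lower in wild type, and 57 were higher and 1 lower in Mll1-/-. The genotype counts were then 577 higher without TNF and 533 higher and 371 lower with TNF. In response, 26 upward genes were higher, 1 downward gene was lower and 1 higher, and the median was -0.24.

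At 1.5-fold the counts were 231 and 83 for TNF in wild type, 721 and 136 in Mll1-/-, 2064 and 2804 for genotype without TNF and 1765 and 1668 with TNF. In response, 92 upward genes were lower and 513 higher, 80 downward genes lower and 46 higher, and the median was 0.67. At 3-fold they were 22 and 5, 29 and 9, 535 and 337, and 509 and 272, with 6 upward genes lower and 16 higher in response and 5 downward genes lower. With the counting interval required as well, 2 genes were lower in wild type and 7 in Mll1-/-, 31 upward genes had a higher response, and 7 downward genes were lower and 1 higher.

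With the 20 most abundant genes left out of the scaling, 38 genes were lower with TNF in Mll1-/-, 623 were lower for genotype without TNF, and the median difference in response was -0.29. Those 20 genes do not dominate a library, and the shift comes from the unequal sums of RPKM. With the length trend removed, TNF in Mll1-/- gave 61 and 58, genotype without TNF gave 704 lower, 22 upward genes were higher and 47 downward genes lower in response, and the median was -0.39. Transcripts of at least 300 bases gave 1 gene lower in wild type, 62 higher and 8 lower in Mll1-/-, 21 upward genes higher, 8 downward genes lower and 0 higher in response, and a median of -0.28. Genes with a symbol gave 15 lower in Mll1-/-, 31 upward genes higher and 12 downward genes lower in response. Both restrictions of length trend and symbol together gave 19 upward genes higher and a median of -0.33.

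The set of genes decides the sign of the median difference in response. Chosen on wild type, 0 upward genes were higher in response with a median of -0.64, and chosen on Mll1-/-, 6 were lower with a median of 0.99, since a gene picked for a large ratio in 1 library pair tends to have a smaller one in the other. Chosen on the mean response, which favours neither, 7 were lower and 3 higher with a median of -0.36. By the increase in RPKM in place of the log2 ratio, 37 upward genes were lower and 71 higher in Mll1-/-.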

Other observations

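Tests chosen after the result was seen were those of the TNF library of the Mll1-/- pair, the swap of 1 library, and the comparison of Xist with other differences between the cultures. The planned list of tests was changed before it was run: a counting-error test for the short transcripts was dropped because the genes were picked on the same difference, and a condition on Ddx3y was added to the Xist test once all values were known. The open test on Xist was also run, taken out for a time and put back.

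Some genes had reads in the cultures of only 1 genotype. At 5 RPKM or more in both wild-type libraries and at 0 reads in both Mll1-/- libraries were 7 genes, among them the lysosomal protease gene Ctsh (11.6 RPKM), the sphingosine phosphate receptor gene S1pr3 (14.7 RPKM) and Thbd. The reverse held for 6 genes, among them Dcn, Hspb1 and Mlkl, of which Mlkl (0 reads against 17.6 RPKM) encodes the executor of necroptosis, a form of cell death that TNF can set off. Wild-type cells with so little Mlkl transcript might be less prone to that death, which a necroptosis assay could test. Mlkl was at least 277-fold higher in Mll1-/- without TNF, and the genotype differences without and with TNF had r = 0.911 across genes.

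The metabolic lists held genes past the size rule at shares not far below that of all genes, which was 2173 of 14386 without TNF. Of 16 NRF2 oxidative stress genes 1 was higher and 1 lower without TNF, of 19 cholesterol synthesis genes 2 were higher and 0 lower (median -0.04, or 0.26 with the 20 most abundant genes left out), and of 21 glycolysis and hypoxia genes 2 were higher and 1 lower. Nqo1, a target of the oxidant sensor NRF2, stood at 24 RPKM in wild type and 120 in Mll1-/-, while the glutathione transferase gene Gsta1 was lower (25.9 against 2.78). The cholesterol synthesis gene Cyp51 (16.3 against 55.9 RPKM) was higher, as were, from other lists, the lipid-uptake gene Lpl (3 reads against 11.6 RPKM, 435-fold, counting interval 148 to 2111) and the imprinted receptor gene Igf2r (3.98 against 29.7), whereas the imprinted growth inhibitor Grb10 was lower (136 against 38.5).

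The smaller response of strong TNF responders in Mll1-/- cells was put against 3 explanations. If the length trend were its cause, the median difference of the 47 genes should vanish without it, but it was -0.48 with 39 genes below 0. Counting error alone would put no more than 3 counting intervals below 0, and 23 lay below and 1 above. A higher starting level in Mll1-/- could shrink a ratio, yet the 22 genes that start no higher still had a median of -0.39, with 15 of the 22 below 0. That is past the bound set for this test by a small margin, given a spread of 0.171 (the standard deviation of the median when the genes are resampled, which covers genes and not libraries). The median of these 22 genes includes the pseudocount and was not taken from reads. Variation between single libraries could not be tested, and the Mll1-/- control library enters every Mll1-/- ratio. Such variation, an effect of Mll1 on NF-kB target promoters and another difference between the cultures all remain open. Independent lines of both genotypes, with replicate libraries, would separate these.

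Whether the larger response of short transcripts in Mll1-/- cells comes from the libraries or from the cells is open. Removal of the length trend left 22 of 48 genes, but the count had to fall, since these genes were picked on the same difference. The TNF library is probably not the odd one, since the genotype difference followed length with a Spearman rho of 0.117 across genes with TNF and 0.34 without it. The Mll1-/- control library may therefore be the one that stands apart, possibly through fragmentation or size selection, and fragment lengths of the 4 libraries would show this.

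Technical causes of the whole genotype difference were weighed as well. A swap of 1 wild-type with 1 Mll1-/- library would turn the correlation of the genotype differences negative, and r was 0.911 across genes, although a swap of both genotype labels would leave it as it is and is not excluded. Of 2173 genes past the size rule without TNF, 1616 stayed past it once the length trend was removed. That count lies just short of the bound set beforehand for setting the trend aside, so its share is open. For copy number of chromosomal segments, 90.2% of 1607 placed genes past the size rule lay outside the blocks described next. The blocks hold only 4.6% of all placed genes, so a high share outside them was likely whatever the cause. They hold 9.8% of the placed genes past the size rule. Segments much shorter than a window of 25 genes would not form a block, so the share due to copy number is open.

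Genes that differ between the cultures lie next to each other more often than in shuffled gene orders. There were 132 neighbouring pairs past the size rule in the same direction in both comparisons, against a median of 58 and at most 86 in 1000 shuffles. Some runs of 3 or more such genes are families that lie together, among them Hoxc10 to Hoxc5, and Mmp13, Mmp3 and Mmp10. A shuffle breaks up such families, so the excess need not come from chromosomal segments. Windows of 25 genes, with settings chosen after an exploratory look had shown the blocks, gave 8 blocks with 512 genes. The longest higher block runs from Decr1 to Txn1 (145 genes, medians 0.81 without and 0.79 with TNF). Within it, the 53 genes between Dnajb5 and Zfp462 outside the runs had medians of 0.74 and 0.79. A gained chromosomal segment in the Mll1-/- culture would give such an even shift, and this may be read from the genomic DNA of the cultures. Tpm2 lies in the higher block and Ldhb in a lower one. Their log2 differences without TNF, 5.07 and -4.95 once the length trend is removed, are far larger in size than the median of any block. A shift of the size of the blocks could therefore account for only a small part of them.

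Xist, the RNA that silences 1 X chromosome in female cells, had 7.06 and 7.84 RPKM in wild type and 4 and 7 reads in Mll1-/-, which is 635.1-fold lower without and 387.4-fold lower with TNF. A second active X would raise X-linked genes, but 358 of them differed from 10751 autosomal genes by only -0.01 without TNF and -0.08 with it. The Y-linked gene Ddx3y gave 0.575 and 0.555 RPKM in wild type and 1.20 and 0.681 in Mll1-/-, possibly with reads from its X-linked copy. The Y-linked genes Uty and Eif2s3y were below the floor of 1 RPKM in every library, too low to give a direction. Uty had 0.152 and 0.103 RPKM in wild type and 0.0381 and 0.0594 in Mll1-/-, and Eif2s3y had 0.0401 and 0.0992 against 0.166 and 0. The Y-linked genes thus do not tell the cultures apart by sex. A difference of sex, a lost X chromosome or another cause of low Xist may lie behind the gap, and the values leave this open because any such difference runs along with genotype in these 4 libraries. Genotyping of sex-linked loci and re-expression of Mll1 in the same Mll1-/- cells could separate the loss of Mll1 from differences of origin.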
